A study of Mus musculus with 8 samples.

How the data were processed

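Polyadenylated RNA of sorted splenic CD4+ T cells was sequenced on an Illumina HiSeq instrument, with 8 libraries in 4 groups of 2. The groups were taken from the library titles and the sort protocol. The submitters' processing notes name TopHat2 2.0.6, Bowtie 1.3.0 and Cufflinks 2.0.2 and the mouse build mm9, with no role or order. Per the file headers, the deposited table holds 1 FPKM value per group, that is fragments scaled to transcript length and to the fragments sequenced, pooled by the authors over the libraries of a group. It also holds, per the file headers, the authors' log2 fold change, a test statistic (a score, not used here), a p-value and a q-value for each of 3 comparisons, with a significance mark, and a cluster number from 1 to 4. The column for effector cells with IL-4 was taken as the Th2 group, the only group outside the Tfh gate. The aligner settings, annotation and depth are not given in the sources used here. Group FPKM values hide the spread between libraries and cannot be turned back into reads, so the depth and precision behind each value are unknown. FPKM is also relative to the sum over a library: a transcript that takes a large part of it lowers the others.

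The table has 1300 rows, of which 80 have no gene name and 64 join several genes. Its rows were chosen by the authors, 767 of them called in at least 1 of the 3 comparisons, so a share of rows is not a share of all genes and a gene outside the table is not shown to be unchanged. Of 1156 single-gene rows, 1149 had a symbol found in the reference name tables as a current or older one. The reference annotation is of another build than mm9, so no coordinates are given. Rows that join genes cannot be split, and their values are uncertain for each gene. Near-identical genes, such as the globins and receptor segments, can share reads and are uncertain for the same reason. The deposited log2 changes were checked against the ratio of the deposited FPKM values: 2 rows differed by over 0.001, Coro2b and Gm3788, both in Tfh21+4 against Tfh21. The significance mark equalled q under 0.05 in every row. The smallest p in the authors' deposited table is 5e-05, which 163 rows of Tfh4 against Tfh21 share, so a low q does not rank these genes. Equal p-values had equal q-values in the 3 comparisons, so q was adjusted over them together; the number of tests is not given in the sources used here.

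The planned analysis assumed values per library, with a linear model on log2(FPKM + 1) and a rotation test for gene lists. As the table holds group values only, no new test between groups was run, and the authors' deposited calls at q under 0.05 were used, with signs turned so that a positive change means higher in the first group named. The other 3 comparisons were described by FPKM ratios without a test. Fold values are plain FPKM ratios, which are unstable for genes near 0, and counts of rows at 2-fold or more use log2(FPKM + 1), which understates low genes. Before the data were examined, 21 gene lists were fixed: Tfh, low in Tfh, Th2, Th1, Th17, regulatory T cell, cytotoxic, B cell help, inhibitory receptor, cell cycle, immediate early, interferon, glycolysis, sterol, chemokine and adhesion genes, and markers of B, myeloid, granulocyte, red, and CD8, NK and NKT cells. Some genes are in several lists. For each list, members were counted by deposited call. The count adjusted over the list alone applied the Benjamini-Hochberg method to the deposited p-values of its members, with members outside the table given a p-value of 1. As the authors chose the rows on these libraries, the lists are not independent evidence of a direction. As a description added after the content of the table was known, the median log2 difference of each list with at least 5 rows was also ranked among 10000 random lists of the same size from the named rows, matched on mean expression in 5 bins.

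Genes were named by a rule fixed beforehand: the sort genes, then for each comparison with deposited calls the 10 higher and 10 lower called genes with the largest log2 change and at least 5 FPKM in the higher group, without unnamed gene models, immunoglobulin and T cell receptor segments and small RNAs, then list members. A few genes that the rule takes are not reported here by name, though counts include them. The receptor segments in the plot of other cell types and the genes that open the other observations were chosen after their values were seen. The position of Tfh21+4 was (Tfh21+4 minus Tfh21) over (Tfh4 minus Tfh21) on the log2(FPKM + 1) scale. Its chance values came from 100 simulations of 3 groups with independent normal values, from which as many rows were picked as the table calls. Alternatives were q under 0.01, a change of at least 2-fold, a mean of at least 5 FPKM, scaling of the groups to 1 median, a pseudocount of 0.1, and, added after the data were seen, named rows only, leaving out marker rows of other cell types, sort genes, joined rows or NK and NKT genes, and scaling for the position and for the split of 2-fold rows. The ranking step was tested on simulated data over 1220 named rows: of 300 lists of 12 rows without a planted shift, 7.33% fell outside the central 95% (exact binomial 95% interval 4.65 to 10.9). A first run with 60 lists had given 10%, after which the number was raised. With a shift of 1 on the log2 scale 80% lay above the central 95%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures by matplotlib 3.10.9.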

Results

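Messenger RNA was measured in CD4+CD44+ T cells sorted from the spleens of mice 8 days after infection with the gut nematode Nippostrongylus brasiliensis, a worm that provokes a type 2 immune response. The mice carried reporters for the cytokines interleukin-21 and interleukin-4. There were 8 libraries in 4 groups of 2. Follicular helper T (Tfh) cells, which help B cells in germinal centres, were gated as CXCR5+PD-1+ and split into cells positive for the IL-21 reporter alone (Tfh21), for both reporters (Tfh21+4) and for the IL-4 reporter alone (Tfh4). The Th2 group was CXCR5-PD-1- and positive for the IL-4 reporter. The sort protocol gives Tfh4 as IL-4 positive, while another label of the same libraries gives it as negative for both reporters; the Il4 values below bear on that. The deposited table held 1300 rows chosen by the authors, with 1 FPKM value per group, so no FPKM below has an SD or an n and the depth per library is unknown. All FPKM values are the authors' group values. The table tested 3 of the 6 possible comparisons, and a row is said to be called, risen or fallen only where its deposited q was under 0.05. The sources used here do not say how the deposited test used the 2 libraries of a group. No label says whether these came from separate mice, so any spread between libraries behind the q values may be technical.

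The genes used for the sort followed the gates. Il21 was at 177 in Tfh21, 142 in Tfh21+4, 20.5 in Tfh4 and 1.02 in Th2 (FPKM), and Il4 was at 5.0 in Tfh21, 166 in Tfh21+4, 193 in Tfh4 and 76.0 in Th2. The Il4 value of Tfh4 was therefore 38.6 times that of Tfh21. Cxcr5, the receptor that brings T cells to follicles, stood at 129 in Tfh21, 225 in Tfh21+4, 152 in Tfh4 and 3.55 in Th2. Pdcd1, which encodes PD-1, was at 228 in Tfh21, 356 in Tfh21+4, 154 in Tfh4 and 7.44 in Th2. Cd4 ranged from 263 in Th2 to 558 in Tfh21. Cd44 was not among the rows. Bcl6, the transcription factor that defines Tfh cells, was highest in Tfh21+4 at 101, against 56.2 in Tfh21, 52.1 in Tfh4 and 7.79 in Th2.

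**Figure D1:**
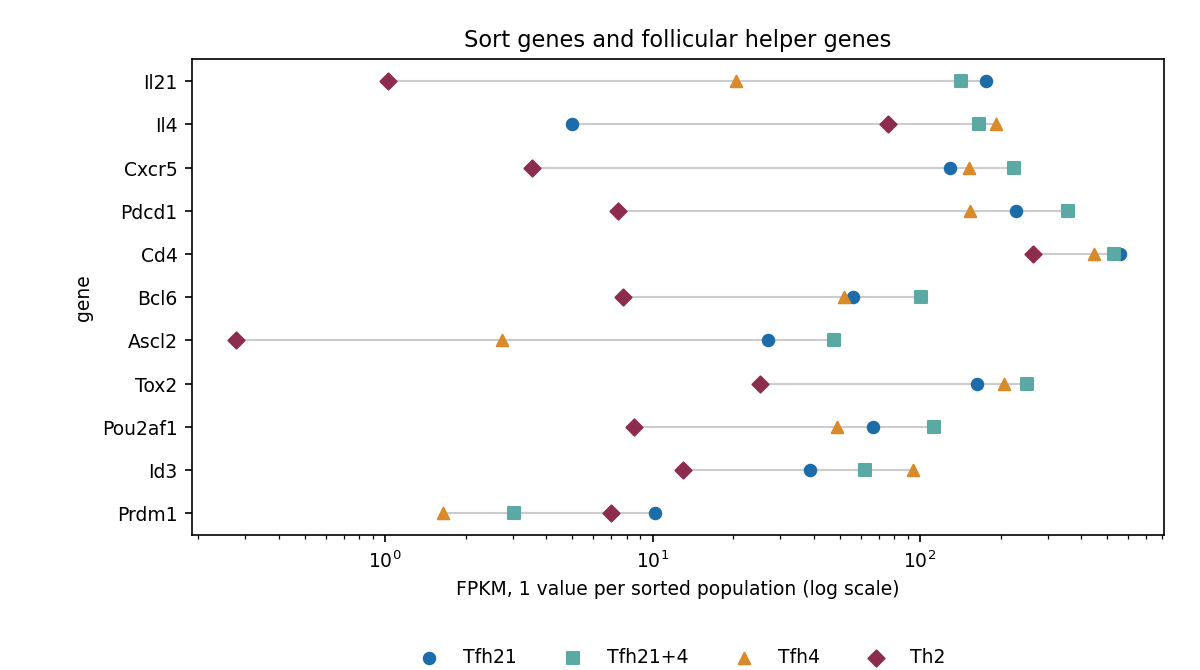
FPKM (horizontal log axis) of the sort genes and of follicular helper genes, with 1 point per sorted population and a grey line over the range of the 4 values. Cxcr5 lies at 3.55 in Th2 and at or above 129 in the Tfh populations, and Ascl2 falls from 47.5 in Tfh21+4 to 2.73 in Tfh4.

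Tfh4 cells were compared with Tfh21 cells to describe how Tfh cells positive for the IL-4 reporter alone differ from those positive for the IL-21 reporter alone. Il4, Il13 and Ccr4 were called higher in Tfh4, and Ifng, Tbx21, Gzmk, Lag3 and Ctla4 lower. Il13, a cytokine of type 2 immunity, was 31.7-fold higher in Tfh4 (q = 0.0105 in the authors' deposited table), an unstable ratio because its Tfh21 value was near 0. Ccr4, a chemokine receptor of Th2 cells, was 6.32-fold higher. Ifng, the signature cytokine of Th1 cells, stood at 97.3 FPKM in Tfh21 and 4.00 in Tfh4, and Il10, a suppressive cytokine, at 50.8 and 3.26. In the authors' deposited table, 343 rows were called, 116 higher and 227 lower in Tfh4. The lower rows made up the larger part, since 33.8% of the called rows were higher (exact binomial 95% interval 28.8 to 39.1, which treats rows as independent). The median log2 FPKM of all rows was also lower in Tfh4 than in Tfh21, by a log2 difference of -0.39. The calls could not be made again under another scaling, so how much of the larger number of lower rows goes with this shift is open.

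Every ranking below takes called genes with at least 5 FPKM in the higher group and leaves out unnamed gene models and receptor segments. For the largest rises the authors' deposited table gives log2 changes of 5.27 for Il4, 4.98 for Il13, 4.39 for Epas1 (the hypoxia-inducible factor HIF-2 alpha), 3.87 for Myo6 (an unconventional myosin), 3.85 for Smtn (smoothelin) and 3.15 for Il1r1 (the interleukin-1 receptor). Rapsn, Satb1, Slc16a5 and Ccr4 completed the 10 largest. Satb1, a chromatin organiser, went from 13.5 FPKM in Tfh21 through 32.3 in Tfh21+4 to 91.1 in Tfh4, and was at 247 in Th2. Under the same floor, the largest falls in the authors' deposited table were -5.99 for Spp1 (osteopontin), -5.73 for Gzmk (granzyme K), -5.71 for Coch, -4.61 for Ifng and -4.09 for Cd109. Ccl4, a row joining Serpina9 with neighbours, Edn3 and Il10 were also among them. Spp1 held 97.1 FPKM in Tfh21 and 94.3 in Tfh21+4 but 1.53 in Tfh4. Of the single genes named here, q in the authors' deposited table ran from 0.0027, the lowest it holds, to 0.0284 for Coch.

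The Tfh list, fixed beforehand, had 26 of its 30 genes in the table. Of these, 2 higher and 7 lower in Tfh4 were called (4 higher and 13 lower when adjusted over the list alone). Without the sort genes, Il21 among them, the count was 2 higher and 6 lower of 23. Lef1 and Id3, transcriptional regulators of early Tfh cells and of T cell maturation, rose, Id3 from 38.8 to 93.9 FPKM. Ascl2, a transcription factor that drives Cxcr5, fell from 27.1 to 2.73 FPKM, and Il21, Irf4, Angptl2, Tnfsf8, Cxcr4 and Cd83 fell as well. Bcl6 itself had a log2 change of -0.11 in the authors' deposited table and was not called (q = 1). Within the Th2 list 13 genes were present, with 4 higher and 3 lower called (6 higher and 3 lower adjusted over the list alone), and without the sort gene Il4 3 higher and 3 lower of 12. Il4, Il13, Ccr4 and Il1rl1, the interleukin-33 receptor, rose, while Il10, Nfil3 and Csf1 fell. Basophil genes stood higher beside them without a call: Mcpt8 went from 8.65 to 22.5 FPKM (q = 0.104 in the authors' deposited table) and Prss34, chosen after its values were seen, from 8.58 to 20.2 (q = 0.09 in the authors' deposited table), and Il1rl1 is itself in the granulocyte and basophil list, of which all 3 genes present were higher in value. Gata3, the Th2 transcription factor, stood in a row joined with a neighbouring transcript, at 47.3 FPKM in Tfh21 and 76.7 in Tfh4, and was not called.

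Of the 17 Th1 genes present, 0 higher and 9 lower were called (1 higher and 11 lower adjusted over the list alone). Tbx21, which encodes the Th1 factor T-bet, fell from 19.8 to 2.74 FPKM, Cxcr3, a chemokine receptor of Th1 cells, from 181 to 22.0, and Eomes from 10.5 to 1.61. The cytotoxic list held 20 genes, 0 higher and 6 lower called (1 higher and 6 lower adjusted over the list alone), and Gzmk, Nkg7, Ccl3, Ccl4, Ccl5 and Crtam fell. For inhibitory receptors the count was 0 higher and 4 lower of 8 (1 higher and 4 lower adjusted over the list alone): Lag3 went from 292 to 31.3 FPKM and Ctla4 from 146 to 42.4, with Havcr2 and Entpd1 also lower. The regulatory T cell list had 0 higher and 6 lower of 10 (0 higher and 6 lower adjusted over the list alone), among them Ikzf2, Nt5e and a row joining Nrp1 with a small RNA gene, whereas a joined row with Foxp3, the factor that defines those cells, was at 6.15 and 10.4 FPKM and not called. Chemokine and receptor genes gave 1 higher and 7 lower of 15 (2 higher and 10 lower adjusted over the list alone). Interferon response genes gave 0 higher and 6 lower of 12 (0 higher and 6 lower adjusted over the list alone). Among them Iigp1 fell from 18.7 to 3.14 FPKM. Calls lower in Tfh4 were common in the whole table, at 227 of 1300 rows. Ranked among the random lists, the cytotoxic median lay at percentile 13.57, so it did not stand out. Percentiles were 0 for Th1 and chemokine genes, 0.15 for regulatory T cell genes and 0.16 for inhibitory receptors. For interferon genes the percentile was 2.15.

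Genes usually low in Tfh cells were mixed, at 3 higher and 6 lower of 23 called (4 higher and 7 lower adjusted over the list alone). Satb1 and Gpr183, a receptor that guides cells to the follicle edge, were among the genes that rose, while Prdm1, the antagonist of Bcl6, fell from 10.2 to 1.65 FPKM. Immediate early genes gave 0 higher and 5 lower of 13 (0 higher and 6 lower adjusted over the list alone), Egr2 and Nr4a1 among the falls. Adhesion genes gave 2 higher and 5 lower of 16 (4 higher and 5 lower adjusted over the list alone). Of these, Itgb3 rose and Itgb8 and Itga4 fell. The immediate early and adhesion medians lay at percentiles 7.87 and 13.79 of the random lists, so neither stood out. B cell help genes gave 1 higher and 3 lower of 7 (2 higher and 3 lower adjusted over the list alone), and without the sort genes Il4 and Il21 0 higher and 2 lower of 5. In the Th17 list 1 higher and 0 lower of 5 were called (1 higher and 0 lower adjusted over the list alone), the rise being Il1r1. Sterol genes gave 2 higher and 0 lower of 4 (2 higher and 0 lower adjusted over the list alone), Srebf2 among them, and glycolysis genes 0 higher and 1 lower of 3 (0 higher and 1 lower adjusted over the list alone), Hif1a. Only 5 of the 100 cell cycle genes were among the rows, with 0 higher and 1 lower called, Ccnd2 (0 higher and 0 lower adjusted over the list alone), so the table says little of proliferation. Of genes of other cell types, 0 higher and 0 lower of 12 red cell genes, 0 higher and 1 lower of 10 CD8, NK and NKT cell genes (Eomes), 0 higher and 1 lower of 12 myeloid genes (Cybb), 1 higher and 0 lower of 8 B cell genes (Fcrl1) and 1 higher and 0 lower of 3 granulocyte and basophil genes (Il1rl1) were called; adjusted over the list alone these were 0 higher and 0 lower, 2 higher and 2 lower, 0 higher and 1 lower, 1 higher and 0 lower and 1 higher and 0 lower. At an unadjusted p under 0.05 the same lists had 0, 5, 6, 1 and 2. Of the myeloid genes 11 were lower in value in Tfh4, with a median log2 difference of -0.66, so a smaller share of myeloid transcripts in Tfh4 is not excluded by the single call.

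**Figure D2:**
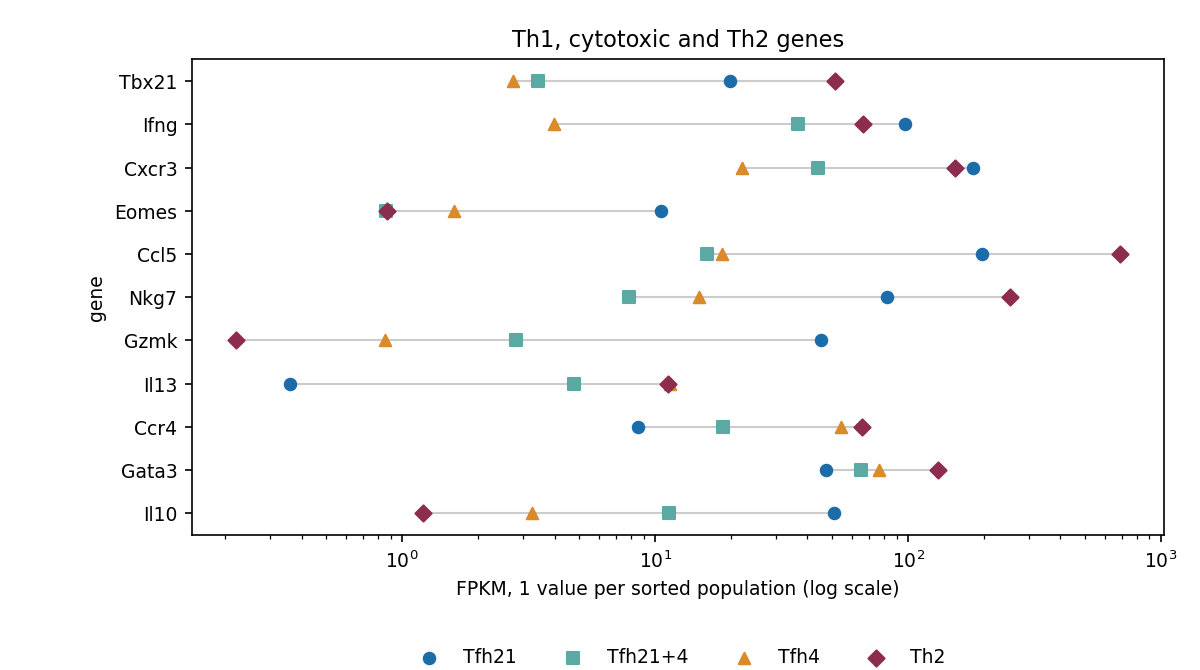
FPKM (horizontal log axis) of Th1, cytotoxic and Th2 genes, with 1 point per sorted population and a grey line over the range of the 4 values. Ifng reaches 97.3 in Tfh21 and 66.1 in Th2 against 4.00 in Tfh4, while Gzmk reaches 45.4 in Tfh21 and 0.221 in Th2.

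Tfh21+4 cells were compared with Tfh21 cells to describe what goes with the IL-4 reporter among cells positive for the IL-21 reporter. Of the Th1 list 9 of 17 genes and of the cytotoxic list 5 of 20 were called lower in the double-positive cells, Bcl6 was called higher, and Il4 was 33.3-fold higher. Ccl5, a chemokine of effector T cells, went from 196 FPKM in Tfh21 to 16.1 in Tfh21+4, Nkg7, a granule protein, from 82.3 to 7.85, and Gzmk from 45.4 to 2.81. Fewer rows were called here than in the comparison above: 163 in the authors' deposited table, 89 higher and 74 lower in Tfh21+4.

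After Il4, the largest called rises with at least 5 FPKM in the higher group in the authors' deposited table were log2 changes of 3.43 for Smtn, 3.23 for Il1r1, 3.12 for Sbk2, 2.79 for Fam71b and 2.55 for C3, the complement component. Sp6, Pipox, Il9r (the interleukin-9 receptor) and Il13ra1 followed. C3 stood at 3.15 in Tfh21, 18.5 in Tfh21+4, 2.00 in Tfh4 and 0.186 in Th2, so that it was highest in the double-positive cells. With the same floor, the largest called falls in the authors' deposited table were -4.90 for a row joining Gpr77 with a small RNA gene, -4.02 for Gzmk, -3.61 for Eomes, -3.60 for Ccl5 and -3.39 for Nkg7. Gcg, Ccl4, Ccl3, Tbx21 and Stk32c completed the 10. Tbx21 had a log2 change of -2.52 (q = 0.0027) in the authors' deposited table.

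In the Tfh list 2 higher and 1 lower of 26 genes were called (11 higher and 1 lower adjusted over the list alone). Bcl6 (0.85, q = 0.0182) and S1pr2 (0.83, q = 0.0422), a receptor that keeps cells within germinal centres, rose on the log2 scale of the authors' deposited table, and Irf4 fell. Of 8 B cell genes present, 6 were higher in value in Tfh21+4 as well and 2 lower, with a median log2(FPKM + 1) difference of 0.67. Whether B cell RNA added to the rises in the Tfh list was not tested. Cxcr5 and Pdcd1 were higher in value in Tfh21+4 but not called (q = 0.154 and 0.242 in the authors' deposited table). Genes usually low in Tfh cells gave 1 higher and 7 lower of 23 (2 higher and 12 lower adjusted over the list alone). Klf2, which restrains Tfh development, fell from 161 to 57.6 FPKM, Ccr7, a receptor for the T cell zone, from 42.9 to 16.9, and Prdm1 from 10.2 to 3.05. The Th1 list had 0 higher and 9 lower of 17 (0 higher and 9 lower adjusted over the list alone), the cytotoxic list 1 higher and 5 lower of 20 (1 higher and 9 lower adjusted over the list alone), and chemokines and their receptors 1 higher and 7 lower of 15 (2 higher and 7 lower adjusted over the list alone). The cytotoxic rise was Ctsl, a cathepsin. Th2 genes gave 3 higher and 1 lower of 13 (3 higher and 1 lower adjusted over the list alone), the rises being Il4, Il13 and Ccr4 and the fall Il10. Beside these rises, all 3 granulocyte and basophil genes present were lower in value in Tfh21+4, with a median log2(FPKM + 1) difference of -0.56.

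Smaller numbers were called elsewhere. Inhibitory receptors gave 0 higher and 2 lower of 8, Lag3 and Entpd1 (3 higher and 3 lower adjusted over the list alone), regulatory T cell genes 0 higher and 1 lower of 10, Il2ra (0 higher and 1 lower, likewise adjusted), and adhesion genes 2 higher and 1 lower of 16, of which Itga4 fell (2 higher and 3 lower, likewise). Immediate early genes gave 1 higher and 1 lower of 13, Dusp4 higher and a row joining Dusp2 with Astl lower (1 higher and 1 lower, likewise). The fixed interferon list had 0 higher and 1 lower of 12 (0 higher and 1 lower, likewise). The lower gene was Cish, and no other gene of that list was called. B cell help genes gave 1 higher and 1 lower of 7, Il4 and Il10 (1 higher and 1 lower, likewise). Th17 genes gave 1 higher and 0 lower of 5, Il1r1 (1 higher and 0 lower, likewise). None of the 5 cell cycle, 4 sterol, 3 glycolysis, 12 myeloid and 3 granulocyte and basophil genes was called by the authors' deposited table, or when adjusted over the list alone, and at an unadjusted p under 0.05 the list of myeloid genes had 1 and the others 0. Red cell genes gave 0 higher and 3 lower of 12 (0 higher and 8 lower adjusted over the list alone), and all 12 were lower in value. Among B cell genes 1 higher and 0 lower of 8 was called, Cd22 (2 higher and 2 lower adjusted over the list alone, and 7 at an unadjusted p under 0.05). The 2 lower genes were Igj and a joined row with Igkc, while Pax5 and Fcrl1 were higher in value without a call. A larger share of B cell transcripts in Tfh21+4 is therefore not excluded by the single call. Among CD8, NK and NKT cell genes 0 higher and 1 lower of 10 was called, Eomes (0 higher and 1 lower adjusted over the list alone).

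The double-positive population was then placed between the single-positive ones, since the series title speaks of progressive differentiation. Epas1 stood at 0.853 FPKM in Tfh21, 4.83 in Tfh21+4 and 17.9 in Tfh4, and Lag3 at 292, 129.7 and 31.3. Spp1 and Cxcr4 instead had close values in Tfh21 and Tfh21+4 and a low value in Tfh4, and Eomes and Ccl5 were already low in Tfh21+4. Of the 116 rows called higher in Tfh4 than in Tfh21, 103 (88.8%) had a Tfh21+4 value between the other 2, with a median position of 0.58 (quartiles 0.37 and 0.73) where 0 is the Tfh21 and 1 the Tfh4 value on the log2(FPKM + 1) scale. Of the 227 rows called lower, 159 (70.0%) lay between, with a median of 0.21 (quartiles -0.05 and 0.54), nearer to Tfh21. Rows picked for a difference between the ends favour middle values. In simulated groups without differences, picked as often, 63.1% lay between and the median was 0.50. Those picks hold noise alone, while the rows here passed q under 0.05, so this share is no exact reference. With the groups scaled to 1 median, 96.6% of the higher and 59.9% of the lower rows lay between, with medians of 0.45 and 0.30, so the lower rows then fell below the simulated share. Over all 1300 rows 43% lay between. Of the 481 rows called in Tfh4 against Th2, 177 (36.8%) lay between. Without those also called in Tfh4 against Tfh21 it was 104 of 375 (27.7%), a choice that favours close end values and so disfavours middle ones. The high shares above are thus tied to picking rows for a difference between the ends. Of the 163 rows called between Tfh21+4 and Tfh21, a choice that favours extreme Tfh21+4 values, it was the highest of the 3 Tfh values in 69 and the lowest in 40.

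**Figure D3:**
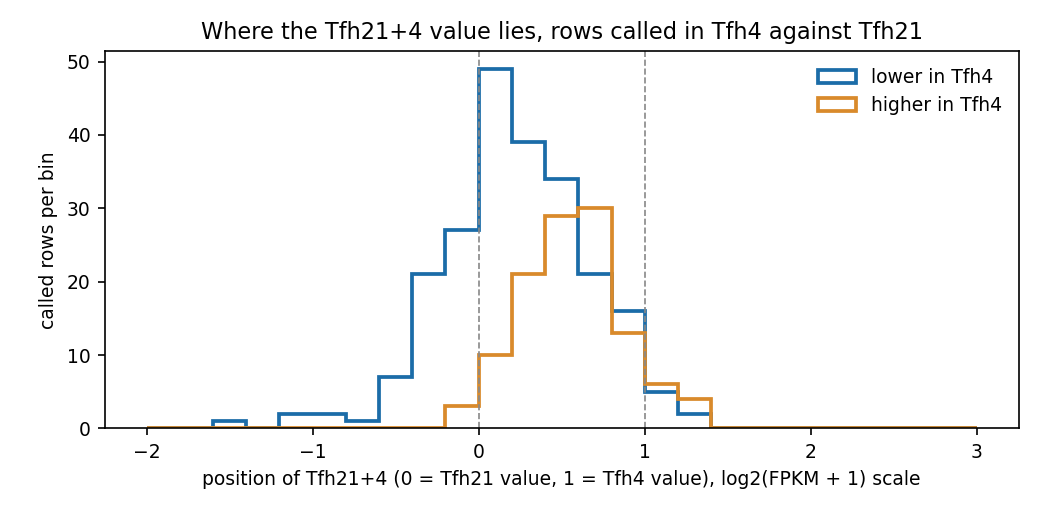
Number of called rows (vertical axis) by the position of the Tfh21+4 value (horizontal axis, 0 at the Tfh21 and 1 at the Tfh4 value, log2(FPKM + 1) scale), for rows called higher and lower in Tfh4 than in Tfh21. Rows higher in Tfh4 centre on 0.58 and rows lower in Tfh4 on 0.21.

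Both comparisons against Tfh21 called 30 shared rows as higher and 40 as lower, among them Il4, Smtn and Il1r1 and, lower, Gzmk, Ccl4 and Tbx21. Independent lists of these sizes would share 7.94 and 12.9. Simulated groups without differences, which share the Tfh21 values, gave 35.6 per direction. Every simulated pick was noise, while the rows here passed q under 0.05. The same simulated value also served both directions, although the list sizes differ. It therefore cannot tell how much of the sharing comes from the common Tfh21 libraries, which could not be split here. Some sharing from them without a shared effect stays possible. Another 6 rows were called higher in Tfh21+4 and lower in Tfh4, and 0 the other way, where the same simulation gave 0.680 per direction. For Tfh4 against Tfh21+4, a comparison without a deposited test, 60 rows were at least 2-fold higher and 258 at least 2-fold lower in Tfh4 on the log2(FPKM + 1) scale. This split rested on the scaling: 18.9% of these rows were higher in Tfh4 as deposited and 59.3% with the groups scaled to 1 median, so no direction is given for the comparison as a whole. Ascl2 was 17.4-fold, Spp1 61.6-fold and Il21 6.91-fold higher in Tfh21+4 by FPKM ratio. Of the Tfh list 0 lay at least 2-fold higher and 10 at least 2-fold lower in Tfh4 on the deposited scale. The list median of -0.64 stood beside a shift of -0.39 in the median log2 FPKM of all rows, so this count can depend on the scaling too. These ratios carry no test.

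Tfh4 and Th2 cells, both sorted for IL-4, were compared to separate the follicular from the effector source of the cytokine. Of the Tfh list 18 of 26 genes were called higher in Tfh4, and 15 of 17 Th1, 11 of 20 cytotoxic and 9 of 10 CD8, NK and NKT cell genes higher in Th2. Cxcr5 was 42.8-fold and Pdcd1 20.6-fold higher in Tfh4, both sort genes. Sostdc1, a secreted antagonist of BMP and Wnt signals, stood at 36.4 FPKM in Tfh4 and 0.533 in Th2. Id2, a regulator opposed to the Tfh programme, was at 84.1 in Tfh4 and 876 in Th2, and Cxcr6 at 42.6 and 458. This was the comparison with the most calls in the authors' deposited table: 481 rows, 240 higher and 241 lower in Tfh4. Il4 was itself 2.54-fold higher in Tfh4, while Il13 was at 11.4 and 11.2 FPKM and not called. The basophil gene Prss34, chosen after its values were seen, was also called higher in Tfh4 (log2 change 1.49, q = 0.0453 in the authors' deposited table). Mcpt8 was higher without a call (1.36, q = 0.103 there), and Il1rl1 was lower without a call.

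On the log2 scale of the authors' deposited table, the largest values for called genes higher in Tfh4, with at least 5 FPKM there, were 6.09 for Sostdc1, 5.42 for Cxcr5, 5.15 for Padi4 (a histone citrullinating enzyme), 4.93 for Cebpa and 4.86 for Fam43a. Il1r2 (the decoy interleukin-1 receptor), Angptl2, Rgs16, Pdcd1 and Il21 followed. Higher in Th2 by the same table of the authors, with the same floor in Th2, were Klrk1 (NKG2D), Xcl1 (lymphotactin), Atp8a2, Serpina3f, Acoxl, Ccl5, Klrd1 (CD94), Mmp9 and Slc27a6, among others. Of these, the authors' deposited table gives -6.37 for Klrk1, -5.84 for Xcl1, -5.23 for Ccl5 and -5.19 for Klrd1, where a negative value means lower in Tfh4. Klrk1 stood at 0.429 FPKM in Tfh4 and 35.4 in Th2.

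In the Tfh list 18 higher and 1 lower of 26 genes were called (21 higher and 2 lower adjusted over the list alone), and without the sort genes 15 higher and 1 lower of 23. Bcl6, Tox2, Pou2af1, Sh2d1a (the signalling adaptor SAP) and Id3 were among the higher genes, and Cd160 was the lower one. Of 8 B cell genes present, 7 were higher in value in Tfh4 as well and 1 lower, with a median log2(FPKM + 1) difference of 1.37. Whether B cell RNA added to the higher Tfh list values was not tested. Genes usually low in Tfh cells gave 1 higher and 10 lower of 23 (1 higher and 12 lower adjusted over the list alone), with Il7r at 15.5 FPKM in Tfh4 and 135 in Th2 and S100a4 the exception in direction. Th1 genes gave 0 higher and 15 lower of 17 (0 higher and 15 lower adjusted over the list alone): Tbx21 was at 2.74 and 51.4 FPKM and Ifng at 4.00 and 66.1. Cytotoxic genes gave 0 higher and 11 lower of 20 (0 higher and 12 lower adjusted over the list alone), with Gzma at 8.12 and 86.3. Beside both lists, CD8, NK and NKT cell genes gave 0 higher and 9 lower of 10 (0 higher and 9 lower adjusted over the list alone), with Klrb1c (NK1.1) at 6.80 and 105 FPKM and Zbtb16, the PLZF factor of innate-like T cells, at 0.444 and 10.5. The 4 joined rows of T cell receptor gamma segments, looked at after their values were seen, were called higher in Th2 as well, the row with Trgv2 at 6.11 and 119.9 FPKM. Without genes that the CD8, NK and NKT list also holds, 15 of 16 Th1 and 8 of 17 cytotoxic genes were called lower in Tfh4. From the Th1 list this removed only Eomes, which was not called, so its count of calls could not change. Genes that remain, such as Tbx21, can be expressed by NKT cells too, so these counts do not separate the lists from such cells.

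The Th2 list gave 2 higher and 3 lower of 13 (2 higher and 4 lower adjusted over the list alone): Il4 and Tnfsf11 were higher in Tfh4, and Nfil3, Il4ra and Plac8 higher in Th2. Chemokine genes gave 2 higher and 7 lower of 15 (3 higher and 7 lower adjusted over the list alone), Cxcr4 and Cxcr5 higher in Tfh4 and Ccr2, Ccr7 and Cxcr6 higher in Th2. B cell help genes gave 5 higher and 0 lower of 7 (5 higher and 1 lower, likewise), among them Slamf6 and Tnfsf8, and inhibitory receptors 3 higher and 2 lower of 8 (3 higher and 2 lower, likewise), with Tigit at 253 FPKM in Tfh4 and 31.4 in Th2. Sort genes added to these counts: without them the Th2 list gave 1 higher and 3 lower of 12, chemokine genes 1 higher and 7 lower of 14, B cell help genes 3 higher and 0 lower of 5 and inhibitory receptors 2 higher and 2 lower of 7. Th17 genes gave 1 higher and 4 lower of 5 (1 higher and 4 lower, likewise), regulatory T cell genes 2 higher and 1 lower of 10 (3 higher and 2 lower, likewise), interferon genes 1 higher and 5 lower of 12 (1 higher and 8 lower, likewise), immediate early genes 1 higher and 3 lower of 13 (4 higher and 4 lower, likewise) and adhesion genes 1 higher and 4 lower of 16 (2 higher and 5 lower, likewise). Slc2a3 among 3 glycolysis genes and Abca1 among 4 sterol genes were the only calls in those lists, both higher in Th2, also when adjusted over the list alone. None of 5 cell cycle genes was called in the authors' deposited table or when adjusted over the list alone over its 100 members, although 5 had an unadjusted p under 0.05 there. Red cell genes gave 9 higher and 0 lower of 12 (11 higher and 0 lower, likewise), B cell genes 6 higher and 1 lower of 8 (6 higher and 1 lower, likewise), myeloid genes 2 higher and 1 lower of 12 (3 higher and 1 lower, likewise) and granulocyte genes 1 higher and 0 lower of 3, Mpo (1 higher and 0 lower, likewise).

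**Figure D4:**
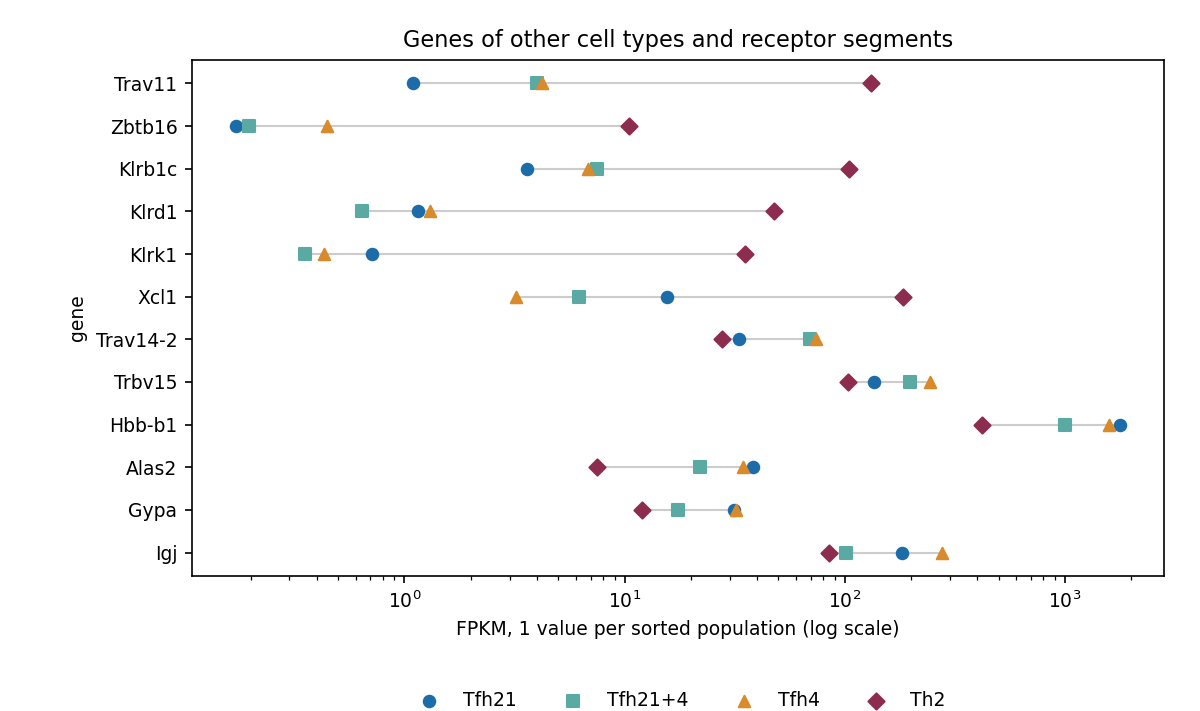
FPKM (horizontal log axis) of NK and NKT cell genes, T cell receptor segments and red cell and plasma cell genes, with 1 point per sorted population and a grey line over the range of the 4 values. Trav11 reaches 132 in Th2 against at most 4.2 in the Tfh populations, and Hbb-b1 falls to 419.7 in Th2.

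The remaining comparisons, Tfh21 and Tfh21+4 against Th2, have FPKM values without a deposited test, and ask how the IL-21-producing cells differ from effector cells. Both had more RNA of Tfh genes and less of NK-type genes than Th2. For Tfh21, 501 rows were at least 2-fold higher and 352 at least 2-fold lower than in Th2, and for Tfh21+4 the numbers were 520 and 352, on the log2(FPKM + 1) scale. The higher rows were 58.7% and 59.6% as deposited and 50.8% and 52.5% with the groups scaled to 1 median. Of 26 Tfh genes 21 lay at least 2-fold higher and 1 at least 2-fold lower in Tfh21, and 23 lay at least 2-fold higher and 1 at least 2-fold lower in Tfh21+4. Of 8 B cell genes 7 lay at least 2-fold higher and 1 at least 2-fold lower in Tfh21. In Tfh21+4 the numbers were 5 and 1. Whether B cell RNA added to the Tfh gene values was not tested. Of 10 CD8, NK and NKT cell genes 1 lay at least 2-fold higher and 9 at least 2-fold lower in Tfh21, and 0 lay at least 2-fold higher and 9 at least 2-fold lower in Tfh21+4. Th1 genes differed between the 2 comparisons in value: 2 lay at least 2-fold higher and 10 at least 2-fold lower of 17 in Tfh21, and 0 lay at least 2-fold higher and 13 at least 2-fold lower in Tfh21+4. Ifng, at 1.47 times its Th2 level in Tfh21, and Eomes, at 10.5 FPKM against 0.873, were higher in Tfh21. These counts carry no test and no error.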

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

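No paired analysis was possible because the table has no values per library. For the same reason leaving out each library, the 2-group fit, the fit without a trend, a pseudocount in the test, the rotation and set tests and a test on recovered reads were not run, so how far a single library decides a call is unknown. At q under 0.01 the calls were 91 for Tfh21+4 against Tfh21, 200 for Tfh4 against Tfh21 and 292 for Tfh4 against Th2, which follows from the stricter limit, and of the last 43.2% were higher in Tfh4 instead of 49.9%. Of 60 named calls 54 also passed 0.01; Il13, Rapsn and Coch in Tfh4 against Tfh21 and Sp6, Stk32c and the Gpr77 row in Tfh21+4 against Tfh21 did not. With a mean of at least 5 FPKM, rows at 2-fold or more numbered 205 instead of 318 for Tfh4 against Tfh21+4, 556 instead of 853 for Tfh21 against Th2 and 569 instead of 872 for Tfh21+4 against Th2, since fewer rows enter. Scaling for the position and for the split of 2-fold rows was chosen after seeing the data. Median log2 FPKM differed by -0.39 for Tfh4 against both Tfh21 and Tfh21+4, -0.24 for Tfh4 against Th2 and 0.14 for Tfh21 and Tfh21+4 against Th2. With these removed, 59.3% of 2-fold rows were higher in Tfh4 than in Tfh21+4 instead of 18.9%, and 50.8% and 52.5% higher in Tfh21 and Tfh21+4 than in Th2. Rows with Tfh21+4 between the other Tfh values became 96.6% of those higher and 59.9% of those lower in Tfh4. As the rows were selected, their median is no neutral reference, and which scaling is closer to the cells was not tested. The deposited calls could not be remade under another scaling. A pseudocount of 0.1 or a 2-fold limit at 5 FPKM moved each median position by less than its quartile spread. Leaving out unnamed rows or marker rows of other cell types, both also chosen after seeing the data, kept each count of calls within 1.5 times. Of 108 pairs of list and comparison, 47 list medians lay outside the central 95% of random lists, or 46 with a pseudocount of 0.1. The nominal rate would give 5.40 and the rate found on simulated data 7.92. The simulated rows were independent, whereas members of a list can move together, and the comparisons share groups. The pairs are therefore not independent, and these counts are a description and no test.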

Other observations

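All tests in this part were chosen after the results they measure were seen. Several genes outside the lists also separated the populations; they were picked after their values were seen. Penk, the precursor of enkephalin peptides, stood at 38.3 in Tfh21, 16.4 in Tfh21+4, 8.66 in Tfh4 and 0.840 in Th2 (FPKM), and Zbtb32, a repressor in activated lymphocytes, at 39.8 in Tfh21, 7.33 in Tfh21+4, 4.01 in Tfh4 and 1.58 in Th2. Gal, which encodes the peptide galanin, was highest in Tfh21+4 at 15.8, against 3.42 in Tfh21 and 1.05 in Tfh4. Vdr, the vitamin D receptor, was at 14.0 in Tfh21, 40.2 in Tfh21+4, 14.9 in Tfh4 and 1.27 in Th2. Lmo4 rose between Tfh21 and both IL-4-positive Tfh populations, from 23.1 to 93.5 and 79.0, and Plagl1 was at 16.3 and 29.5 in the IL-21-positive populations and 2.64 in Tfh4. In the authors' deposited table, Penk, Zbtb32 and Plagl1 were called lower in Tfh4 than in Tfh21, and Vdr and Gal higher in Tfh21+4 than in Tfh21.

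The table was wider than its 3 tests: 533 rows were called in none of them. Of these, 389 differed at least 2-fold in at least 1 comparison without a test, and 123 in at least 1 with a test. A row without a gene name held 632847 FPKM in Th2, 87.8% of the sum over the rows, against 165056 in Tfh21+4. A share of summed FPKM is not a share of fragments. The named rows summed to 51147 FPKM in Tfh21, 46727 in Tfh21+4, 48854 in Tfh4 and 50061 in Th2, so these sums were close.

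Genes of NK and NKT cells were high in the Th2 value, with a median log2(FPKM + 1) difference from Tfh4 of 3.12 over 10 list genes, 7 of which are also in other lists. A scaling difference is argued against, as the median over all named rows was -0.28 and the lower quartile of the list 2.00. A candidate explanation is NKT cells inside the CXCR5-PD-1- IL-4 reporter gate, of which the CD4 gate would remove only those without CD4. Trav11, the variable segment of the invariant NKT receptor, was 31.5 times as high in Th2 as in the highest Tfh value, against at most 0.376 times for 3 other alpha segments, with Cxcr6 at 458 and Klrb1c at 105 FPKM. Conventional effector cells with NK receptors cannot be told apart from NKT cells for genes that both can express, since the value pools cells. Tbx21, such a gene, was higher in Th2 by 3.81 on that scale. A part of gamma delta T cells, which the CD4 gate would mostly remove, stays open too. The 4 gamma segment rows had a median Tfh4 minus Th2 difference of -2.99. A row joining the delta segments Trdj1 and Trdj2 went the other way without a call. Its log2 change for Tfh4 against Th2 was 0.48 in the authors' deposited table.

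Red cell genes were lower in Tfh21+4 than in Tfh21, with a median difference of -0.82 on the log2(FPKM + 1) scale, and higher in Tfh4 than in Th2 by a median of 1.43. Between Tfh21+4 and Tfh21 the 12 genes moved together (SD 0.104 against 0.729 over all named rows), which is consistent with red cell RNA carried over in different amounts, although a CD4 gate would remove red cells. Against Th2 they moved less alike, with an SD of 0.565 between Tfh21 and Th2 against 1.76 over all named rows, so carry-over and other sources cannot be told apart there by this spread; Hba-a2 was at 3674 FPKM in Tfh21 and 904 in Th2. A single admixture that also brings immunoglobulin RNA stays open for Tfh21+4 and Th2 against Tfh21, where the median of 14 immunoglobulin rows minus that of red cell rows was -0.10 and, for Tfh21 against Th2, -0.08, within the larger semi-interquartile ranges of 0.430 and 0.476. For Tfh4 it is argued against, as the difference was 0.77 against Tfh21, 0.68 against Tfh21+4 and 0.44 against Th2, beyond the ranges of 0.248, 0.378 and 0.359, and no biological explanation was tested.

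Th1 genes were high in Tfh21 as well as in Th2, with a median Tfh21 value of 41.5% of the Th2 value over 17 genes (lower quartile 28.5%). NKT cells inside the Tfh21 gate are argued against as the source, since 6 NKT genes (Trav11, Zbtb16, Klrb1c, Klrk1, Klrd1 and Klrc1) reached a median of 1.97% of their Th2 value in Tfh21, with a highest of 3.42%. These 6 genes were picked after their values were seen, and Trav11 and Klrc1 are outside the fixed CD8, NK and NKT list. Of that list, Cd160 stood at 12.4 FPKM in Tfh21 and 84.1 in Th2, and Eomes was higher in Tfh21. Its 10 genes had a median log2(FPKM + 1) difference Tfh21 minus Th2 of -3.38 (1 higher and 9 lower). For the 17 Th1 genes it was -1.22. Whether every Tfh21 cell or a part of them held the Th1 genes stays open, as does a difference in cell state between the reporter populations.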
